A study of Saccharomyces cerevisiae with 5 samples.

How the data were processed

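Mononucleosomal DNA of 5 *S. cerevisiae* strains was measured, 1 library per strain: YAC1, YAC2 and YAC3 with artificial chromosomes from *K. lactis*, YAC6 and YAC7 with artificial chromosomes from *D. hansenii*. Per the labels' protocols, cells were grown without added tryptophan and uracil and with 2% dextrose, turned into spheroplasts with zymolyase and digested with micrococcal nuclease, and the gel-purified mononucleosomal DNA was made into Illumina libraries. Per the submitters' processing notes, CASAVA 1.7.0 was used. The aligner, the genome builds, any extension of reads and the origin of the start sites are not given in the sources used here.

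Each library came as a table of host genes and a table of insert genes. Per the file headers, the values are signal (coverage of nucleosomal DNA) in 151 bins of 10 bp from -500 to +1000 bp of the start site, oriented by gene. The deposited signal is never negative, has a mean near 1 per table and steps in whole multiples of 1 unit per table (100% of values within a tolerance of 0.02 steps), so the authors scaled it, but not to reads. That unit was the same in the host and insert table of YAC2, YAC3 and YAC6. It was 1.77 times larger in the insert table of YAC1 and 1.29 times larger in that of YAC7. The YAC2 insert file holds a further table of the same 37 genes with every gene divided by its total, which was not used here. For 214 host genes the suffix letter of the systematic name stood in the strand column and was put back. Gene symbols came from a gene table of *S. cerevisiae* assembly R64, in which 5261 of 5264 host genes had an entry. Its positions served only to order host genes along chromosomes, since the build of the tables is not given, and foreign genes are named by their identifiers. That order underlies the neighbouring host sets and the left and right parts and sides of chromosomes. Depth is therefore known only as steps, 396 to 1739 per bin on average in the host tables, and no counting interval was computed. Intervals are 95% bootstrap intervals over genes (2000 draws).

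The promoter ratio of a gene is log2 of the mean signal from -120 to -20 bp over that from +100 to +500 bp, after adding 0.1 times the gene's mean signal to both. This pseudocount makes differences at strongly depleted promoters smaller. Both windows are the same for every gene, whatever its length, and a low signal from +100 to +500 bp also raises the ratio. Genes with a mean signal under 10% of the host median were left out, which kept 5254 to 5258 host genes per library and removed 1 insert gene, KLLA0F10857g of YAC1. Gene-body depletion is log2 of the lowest 100 bp mean from +200 bp onward over the mean of that stretch, with the same pseudocount. The window runs to +1000 bp for every gene, whatever its length. The +1 position, the spacing and the amplitude were read from mean profiles with each gene scaled to its mean and smoothed with a Gaussian of SD 20 bp. The +1 position is the highest point between 0 and 150 bp. Each next peak was sought 120 to 230 bp further, spacing is the slope through up to 4 peaks (at least 3), and amplitude covers the first 3 peaks. The autocorrelation peak of single genes was read from the mean of the genes' autocorrelation curves. It was added after the data were seen.

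The main windows, filters, tests, gene lists and the rule for named genes were fixed before the data were examined. Species comparisons of the +1 position, spacing and amplitude, and gene draws between species, were not in that plan. Insert medians were compared with 100000 random host gene sets of the same size from the same library (two-sided permutation tests, p = 2e-05 at the least), averaged over the strains of a group. Strain values were compared between species by an exact permutation test, where 10 splits allow no p under 0.1, and with 0 by an exact sign-flip test over 5 strains, where no p under 0.0625 is possible. Host lists were compared with 100000 random host sets. Host promoter ratios of 5252 genes were compared between the strain groups with limma (empirical Bayes with a mean trend) and a threshold of 0.05. Benjamini-Hochberg adjustment was used within each family: 30 tests by strain, 16 by group, 6 between species, 12 lists. A planned count model had no counts to run on, since the values are scaled coverage. Named insert genes are the 3 lowest and 3 highest promoter ratios and the 2 deepest gene-body stretches of each strain. Named host genes are the 2 lowest and the 1 highest of each list, both markers, and, since none passed in limma, the 2 per direction with the smallest unadjusted p, of which 3 of the 4 are printed. The lists were ribosomal protein, glycolysis and fermentation, histone, heat shock and stress, galactose, phosphate, meiosis and sporulation, PAU and COS symbols (listed as subtelomeric), ribosome biogenesis, proteasome, general regulatory factor and remodeller, and the YAC selection markers.

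The alternatives were other windows, pseudocounts of 0.5 and 0.02, filters of 0 and 50%, means in place of medians, other smoothing, unscaled profiles, host sets matched on signal, and leaving out each strain in turn. Added after the data were seen were host sets of neighbouring genes, leaving out chromosomes II and X, leaving out genes with a run of 10 bins at 0, insert windows moved with the +1 nucleosome, centring of libraries, levels in steps and spacing by autocorrelation. The insert tests were checked on 400 random host sets per library used as fake inserts: 2.75 to 7.25% came out below 0.05, and a filling of 0.5 (log2) was detected in 62 to 99%. The fake inserts were drawn gene by gene from the same pool as the null sets, so a rate near the threshold was built in. This check does not cover false calls for inserts that are runs of neighbouring genes. Shifts of -15 bp were recovered as -15.0 to -14.9 bp. Synthetic arrays of 40 to 100 genes gave spacing within 0.339 bp and the +1 position within 3.14 bp. The limma step was tested on simulated data for 5252 genes. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1 were used.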

Results

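Nucleosomes were mapped in 5 *Saccharomyces cerevisiae* strains, each carrying foreign yeast DNA on a yeast artificial chromosome (YAC), a linear vector that is copied and segregated like a host chromosome. The inserts of strains YAC1, YAC2 and YAC3 came from *Kluyveromyces lactis*, and those of YAC6 and YAC7 from *Debaryomyces hansenii*. Each strain gave 1 library of mononucleosomal DNA after digestion with micrococcal nuclease, so the replicates within a group (n = 3 and n = 2) are different strains. Their inserts differ too, apart from 9 genes shared by YAC2 and YAC3. The design asks how host cells package DNA that did not evolve with them, with the host genes of the same library as the reference. Each library held 5264 host genes, and its insert held 58, 37, 39, 52 and 102 genes in the order YAC1, YAC2, YAC3, YAC6, YAC7. Depth in reads is unknown. Counted in the smallest step between values of a host table, the mean host signal was 1739 steps in YAC1, 559 in YAC2, 396 in YAC3, 1479 in YAC6 and 726 in YAC7, so YAC3 was the coarsest library and YAC1 the finest.

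Promoters of the foreign genes carried a nucleosome-depleted region in all 5 strains, but by the median promoter ratio a shallower one than host promoters of the same cells. The measure is the log2 ratio of the signal from -120 to -20 bp of the listed start site to the signal from +100 to +500 bp, where lower values mean deeper depletion. Median ratios of *K. lactis* genes were -1.59 in YAC1, -1.29 in YAC2 and -1.31 in YAC3, against host medians of -2.28, -1.76 and -1.74. Those of *D. hansenii* genes were -0.74 in YAC6 and -0.997 in YAC7, against host medians of -2.27 and -1.89. The insert median thus lay above the host median by 0.53 ± 0.14 (SD, n = 3) for *K. lactis* and by 1.21 ± 0.46 (SD, n = 2) for *D. hansenii*. Both differences reached p = 2e-05, the smallest that the permutation test with 100000 draws of host genes can give (two-sided, adjusted p = 4.57e-05 over 16 tests). By strain, they were 0.69 in YAC1 (permutation test, adjusted p = 0.00132 over 30 tests), 0.47 in YAC2 (adjusted p = 0.0328), 0.44 in YAC3 (adjusted p = 0.0872, not past 0.05), 1.54 in YAC6 and 0.89 in YAC7 (both adjusted p = 8.57e-05). These tests treat genes as units and genes are not independent replicates. With the 5 strains as units, the exact sign-flip test gave p = 0.0625, the smallest that 5 strains allow, with insert promoters shallower in 5 of 5. A pseudocount of 0.5 in place of 0.1 times the gene mean lowered the differences to 0.23 and 0.63, and means in place of medians lowered the *K. lactis* value to 0.35. Against runs of neighbouring host genes, an alternative chosen after the data were seen, the permutation p was 0.256 for *K. lactis* and 0.0828 for *D. hansenii*, and it was 2e-05 for both once chromosomes II and X, whose listed start sites lie off the nucleosome pattern, were left out. In that last setting YAC3 alone gave 0.54 (permutation p = 0.00766, unadjusted).

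**Figure D1:**
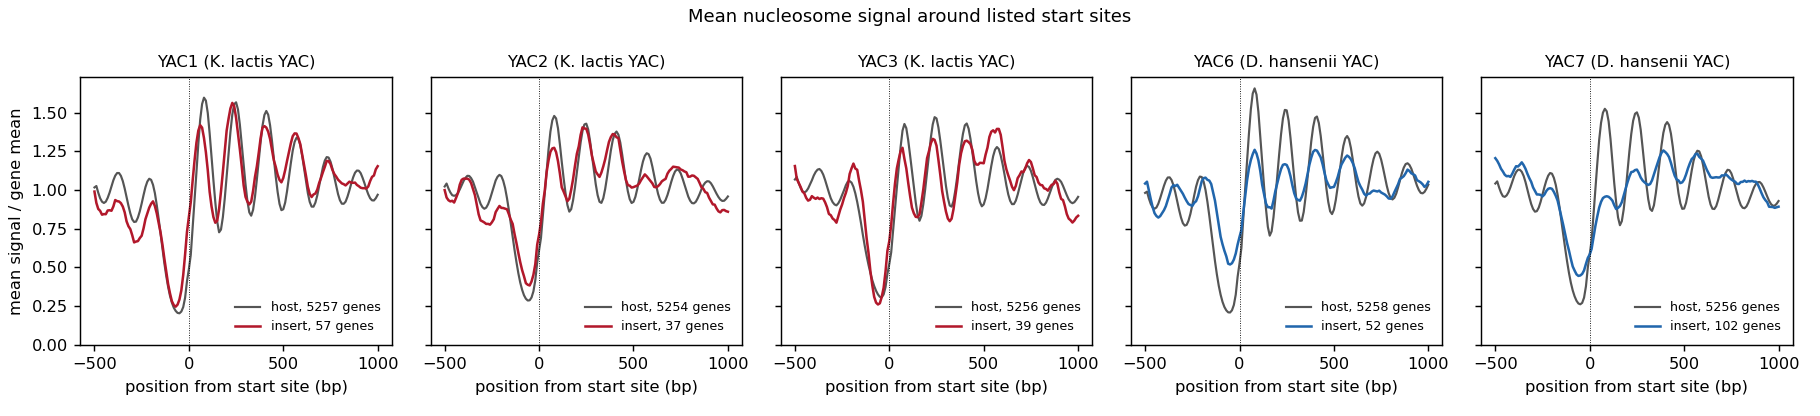
Mean nucleosome signal, each gene scaled to its own mean, against distance from the listed start site in bp, for host genes and insert genes of each of the 5 strains. The lowest point of the insert profile lies at 0.519 in YAC6 and 0.445 in YAC7, above the host's 0.209 and 0.262, and at 0.246, 0.383 and 0.261 in YAC1, YAC2 and YAC3, against the host's 0.204, 0.286 and 0.307, so that the YAC3 insert lies below its host here, and above it (0.248) once chromosomes II and X are left out of the host.

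Fewer foreign genes than host genes had a promoter ratio below -1, in 5 of 5 strains. Below that line lay 45 of 57 *K. lactis* genes past the signal filter in YAC1 (78.9%), 24 of 37 in YAC2 (64.9%) and 24 of 39 in YAC3 (61.5%), against 84.4%, 77.01% and 73.4% of host genes. Of the *D. hansenii* genes it was 21 of 52 in YAC6 (40.4%) and 51 of 102 in YAC7 (50%), against 82.5% and 77.5% of host genes. Promoters with more signal than the gene body, a ratio above 0, numbered 1 in YAC1, 0 in YAC2, 0 in YAC3, 6 in YAC6 and 15 in YAC7. As shares these are 1.75%, 0%, 0%, 11.5% and 14.7%, against 5.08%, 6.30%, 9.63%, 5.63% and 6.91% of host genes. Displaced start sites raise these host shares. Without chromosomes II and X, left out after the data were seen, they were 1.90%, 3.19%, 6.75%, 2.12% and 3.89%, with 1.75% in YAC1 close to its host. These shares describe the 5 inserts and were not tested.

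The deepest foreign promoters reached the lowest 5 percent of host promoters in YAC1 and YAC7, but not in the other strains. In YAC1 the lowest ratios were those of KLLA0F10175g (-3.51), KLLA0F09889g (-3.42) and KLLA0F09669g (-3.16), and KLLA0F10175g ranked at the 3.31 percentile of host genes. In YAC2 they were those of KLLA0C04235g (-2.73), KLLA0C03850g (-2.51) and KLLA0C04059g (-2.44), and in YAC3 those of KLLA0C06336g (-3.04), KLLA0C05346g (-2.64) and KLLA0C06446g (-2.50). DEHA2D15048g (-3.53, the 1.50 percentile of host genes), DEHA2D14300g (-3.26) and DEHA2D14212g (-3.16) were lowest in YAC7. The lowest *D. hansenii* promoters of YAC6, DEHA2C14080g (-2.87), DEHA2C14498g (-2.85) and DEHA2C13552g (-2.58), lay only at the 25.3 to 38.4 percentiles of the host. DEHA2C13552g has 41 of 151 bins at 0, so its low ratio may rest on missing coverage.

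At the other end, the highest ratios in YAC1 were those of KLLA0F10198g (0.67), KLLA0F09647g (-0.16) and KLLA0F09757g (-0.36). In YAC2 they were those of KLLA0C04730g (-0.04), KLLA0C04367g (-0.19) and KLLA0C05302g (-0.25), and in YAC3 those of KLLA0C06490g (-0.32), KLLA0C06050g (-0.32) and KLLA0C06358g (-0.38). The *D. hansenii* genes with the most filled promoters were DEHA2D13684g (1.74), DEHA2D13728g (1.02) and DEHA2D14080g (0.85) in YAC7, and DEHA2C14344g (0.39) and DEHA2C13508g (0.13) in YAC6. DEHA2C13244g of YAC6 stood at 4.38, but 85 of its 151 bins hold 0 and its signal from +100 to +500 bp is 0.00339, so its ratio rests on the pseudocount. The tables do not pair the foreign genes with names, and each of these values comes from 1 library.

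**Figure D2:**
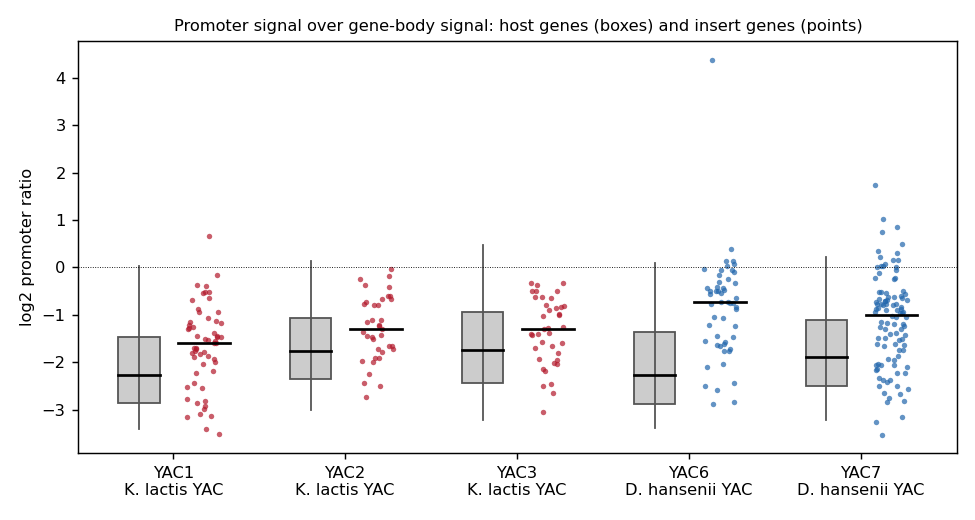
Log2 promoter ratio of host and insert genes in each strain (box, 25 to 75% of genes; whiskers, 5 to 95%; black line, median). Insert medians lie above host medians in 5 of 5 strains, with the widest gap, 1.54, in YAC6 and the narrowest, 0.44, in YAC3.

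The gap between insert and host promoters was smaller for *K. lactis* than for *D. hansenii* by 0.68 (difference -0.68). All 3 *K. lactis* strains lay below both *D. hansenii* strains. With strains as units the exact permutation test gave p = 0.1, the smallest that 3 strains against 2 allow, so this test cannot pass 0.05. Draws of host genes gave p = 6e-05 (permutation test, adjusted p = 0.00012 over 6 tests), which covers chance among genes of these strains only. Without YAC6 the difference was -0.36, and with a pseudocount of 0.5 it was -0.40.

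From +200 to +1000 bp of the start, here called the gene body, the median foreign gene held no deeper depleted stretch than the median host gene. The measure is the lowest 100 bp from +200 bp onward over the mean of that stretch, on the log2 scale. Gene ends were not used, so a depleted stretch can lie past the end of a shorter gene. *K. lactis* genes were slightly less depleted than host genes, by 0.12 ± 0.07 (SD, n = 3, permutation test, adjusted p = 0.0254). *D. hansenii* genes differed by 0.07 ± 0.09 (SD, n = 2, permutation test, adjusted p = 0.0891), which does not pass 0.05. The 2 species differed by 0.05, with an exact permutation p of 0.6 across strains and 0.465 by gene draws. Without YAC6 the *D. hansenii* value was 0.13 (permutation p = 0.0214) and the species difference turned to -0.01. The *K. lactis* call rested on YAC1, where the difference was 0.19, and without YAC1 it was 0.08 with a permutation p of 0.283. Runs of neighbouring host genes gave it p = 0.0534 (permutation test), and stretches of 50 bp gave 0.21 for *K. lactis* and 0.17 for *D. hansenii*, and means in place of medians gave 0.27 and 0.11, all past the threshold. A pseudocount of 0.5 gave 0.06 for *K. lactis*. The deepest single stretches were those of KLLA0F09790g (-2.52) and KLLA0F10351g (-1.81) in YAC1, KLLA0C04620g (-1.70) and KLLA0C05302g (-1.55) in YAC2, and KLLA0C05016g (-2.57) and KLLA0C05610g (-1.87) in YAC3. Among *D. hansenii* genes they were those of DEHA2C14542g (-2.94) and DEHA2C14520g (-2.57) in YAC6, and DEHA2D14344g (-2.96) and DEHA2D15070g (-2.86) in YAC7. Host genes with deeper stretches made up 1.92% of the total for DEHA2D14344g and 23.2% for KLLA0C05610g, the lowest and highest of those named.

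The first nucleosome downstream of the start site, the +1 nucleosome, lay closer to the listed start in *K. lactis* genes than in host genes on the mean of 3 strains, but YAC2 alone did not pass. In the mean host profiles it peaked at 82.4, 81.9, 83.1, 79.6 and 80.6 bp in YAC1, YAC2, YAC3, YAC6 and YAC7. In the inserts it peaked at 62.2, 75.3 and 66.03 bp for *K. lactis* and at 79.5 and 92.6 bp for *D. hansenii*. The difference was -14.6 ± 7.11 bp (SD, n = 3) for *K. lactis*, with p = 2e-05 in the permutation test, and 5.92 ± 8.53 bp (SD, n = 2) for *D. hansenii*, with p = 6e-05. In YAC2 it was -6.62 bp with a 95% interval of -15.8 to 4.545 bp over genes (permutation test, adjusted p = 0.0872). The *D. hansenii* value came from YAC7 alone, at 11.9 bp with a 95% interval of -2.89 to 64.4 bp over genes. Without YAC7 it was -0.107 bp with a permutation p of 0.963, and against runs of neighbouring host genes p was 0.441. Over all 5 strains the mean was -6.41 ± 13.0 bp (SD, n = 5), below 0 in 4 of 5 strains, with p = 2e-05 by gene draws and 0.312 in the exact sign-flip test. Leaving out YAC1 ended that call (-2.97 bp, permutation p = 0.0861), and without YAC7 the mean was -11.0 bp. Between the species the position differed by -20.6 bp (exact permutation p = 0.1 across strains, 2e-05 by gene draws). Gene draws carry the spread of host sets, not that of the position in the inserts. The source of the listed start sites is not given for either genome, and an offset between the sources would move this position.

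Regular arrays of nucleosomes downstream of the start were less sharply lined up in foreign genes than in host genes, in 5 of 5 strains. Amplitude, the log2 ratio of a peak to the next trough averaged over the first 3 peaks of the mean profile, was 0.50, 0.31 and 0.38 in the *K. lactis* inserts against 0.69, 0.49 and 0.53 in the host. In the *D. hansenii* inserts it was 0.28 and 0.11 against 0.71 and 0.61. The difference was -0.17 ± 0.02 (SD, n = 3, permutation test, p = 6e-05) for *K. lactis* and -0.47 ± 0.05 (SD, n = 2, permutation test, p = 2e-05) for *D. hansenii*. YAC3 alone did not pass, at -0.15 with a 95% interval of -0.26 to 0.01 over genes (permutation test, adjusted p = 0.0596). Against runs of neighbouring host genes without chromosomes II and X, chosen after the data were seen, YAC3 gave -0.20 (permutation p = 0.0211, unadjusted). The 5 strains together gave -0.29 ± 0.16 (SD, n = 5), with an exact sign-flip p of 0.0625. The species differed by 0.29 (exact permutation p = 0.1 across strains, 2e-05 by gene draws). A measure that needs no common start site, the peak height of the mean autocorrelation curve of single genes, was lower by gene draws in *D. hansenii* (-0.112 ± 0.0183, SD, n = 2, permutation p = 2e-05). Differences in spacing from gene to gene also lower it. In *K. lactis* it gave -0.0435 ± 0.0545 (SD, n = 3, permutation p = 0.0780), with YAC2 at -0.106, YAC1 at -0.0145 and YAC3 at -0.00957. Without YAC2 it was -0.0121, and without YAC3 -0.0605 with a permutation p of 0.0328.

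The distance between neighbouring nucleosomes was near 163 bp in host genes, between 162.7 and 164.0 bp in the 5 libraries. In the inserts it was 167.9, 161.9 and 166.7 bp for *K. lactis* and 164.2 and 157.7 bp for *D. hansenii*. The difference from the host was 2.34 ± 3.25 bp (SD, n = 3, permutation p = 0.128) for *K. lactis* and -2.67 ± 5.19 bp (SD, n = 2, permutation p = 0.00582) for *D. hansenii*. Over the 5 strains it was 0.337 ± 4.42 bp (SD, n = 5, permutation p = 0.726), and -0.682 bp without YAC1, -0.582 bp without YAC3 and 2.01 bp without YAC7. The *D. hansenii* call came from YAC7, at -6.34 bp with a 95% interval of -15.05 to 45.45 bp over genes, which leaves its sign unsettled, and without YAC7 the sign turned (1.00 bp, permutation p = 0.468). The *K. lactis* value without YAC2 was 4.21 bp with a permutation p of 0.0249. Spacing read from the autocorrelation of single genes gave -0.147 bp for *K. lactis* and 0.878 bp for *D. hansenii*, neither past the threshold. These means cover strains of opposite sign, 5.86 bp in YAC6 (permutation p = 2e-05) against -4.10 bp in YAC7 (permutation p = 0.0187), and 3.76 bp in YAC1 (permutation p = 0.0061) against -3.76 bp in YAC2 and -0.442 bp in YAC3, all unadjusted.

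The 9 genes that YAC2 and YAC3 share gave like profiles in both strains. Across the bins of a gene, the correlation between the 2 libraries had a median of 0.877 (range 0.787 to 0.964), against 0.869 for host genes. Promoter ratios of KLLA0C05368g were -0.80 in both strains, and KLLA0C05082g gave -1.50 and -1.31. KLLA0C04906g differed most, with -1.22 in YAC2 and -1.95 in YAC3. The median absolute difference was 0.40 for the 9 genes and 0.39 for host genes, so the foreign genes differed between these libraries by about as much as host genes did. KLLA0C05368g, KLLA0C05082g and KLLA0C04906g were picked from this set after their values were seen.

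Among host genes, promoter depletion differed between functional groups chosen before the data were examined. Ribosome biogenesis and proteasome genes had the deepest promoters relative to the host median of -1.99. For ribosome biogenesis, 26 of 31 genes lay below the host median and the list median differed from it by -0.62 ± 0.09 (SD, n = 5 libraries, permutation test, adjusted p = 0.00084 over 12 lists). MAK16, which is needed for large-subunit maturation, stood at -3.70 ± 0.25, and NOP1, the fibrillarin of the yeast nucleolus, at -3.51 ± 0.47. The proteasome list differed by -0.57 ± 0.11 (permutation test, adjusted p = 0.00232), with 24 of 31 genes below the median and PRE8 (-3.48 ± 0.26) and PRE4 (-3.45 ± 0.14), both core particle subunits, lowest. The highest members, MPP10 (1.68 ± 0.33), a small-subunit processing factor, and PRE3 (0.24 ± 0.14), a catalytic core subunit, lie on the part of chromosome X whose start sites are displaced.

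Several groups of regulated genes had shallower promoters than the median host gene, in 5 of 5 libraries each. Genes with PAU or COS symbols, listed beforehand as subtelomeric, differed by 1.55 ± 0.32 (SD, n = 5, permutation test, adjusted p = 0.0111) with 5 of 6 genes above the median. Their extremes were PAU10 at 2.94 ± 0.28 and COS10 at -1.99 ± 0.35, next to COS111 at -0.87 ± 0.18 on the displaced part of chromosome II. By systematic name COS111, PAU17 and PAU23 lie inside their chromosomes, so the list is not a subtelomeric set. Without chromosomes II and X, and so without COS111, the difference was 1.75 (permutation test, adjusted p = 0.00368). Members of gene families can share reads with near-identical copies, so single values are uncertain. Histone genes differed by 0.98 ± 0.36 (permutation test, adjusted p = 0.0228) with 10 of 11 above the median. The H4 gene HHF2 stood at 0.76 ± 0.75, while CSE4, the centromeric histone H3 variant, was at -2.74 ± 0.25 and HTZ1, the H2A.Z gene, at -1.86 ± 0.72. Galactose genes, repressed on glucose, differed by 0.97 ± 0.07 (permutation test, adjusted p = 0.0400) with 7 of 9 above. GAL3, the galactose sensor, was at 1.28 ± 0.37, and the regulators GAL80 and GAL4 were at -2.83 ± 0.04 and -2.30 ± 0.28. By systematic name GAL3 lies near the YAC marker TRP1. Its signal was 1.73 (YAC2) to 2.12 (YAC7) times its chromosome's median, against 1.63 (YAC1) to 2.13 (YAC3) for TRP1. Vector copies that reach GAL3, where present, would add to its signal, which was not tested. Phosphate genes differed by 0.93 ± 0.15 (permutation test, adjusted p = 0.0103) with 13 of 16 above. VTC3, of the polyphosphate polymerase complex, was at 0.28 ± 0.87 with -1.22 in YAC6 (0.66 without YAC6, 0.14 without YAC2, 0.12 without YAC7), VTC1 of the same complex at -3.07 ± 0.33 and the transcription factor PHO4 at -2.90 ± 0.54. Meiosis and sporulation genes differed by 0.63 ± 0.11 (permutation test, adjusted p = 0.0167) with 20 of 26 above. The lowest were SPO11, the nuclease that starts meiotic recombination, at -3.45 ± 0.44 and the septin SPR28 at -3.03 ± 0.35. The master regulator IME1 was at 1.03 ± 0.38 on the displaced part of chromosome X. The histone list lost its call with the wider window from -150 to -1 bp (0.73, permutation test, adjusted p = 0.0697). The galactose list lost it with that window (0.79, adjusted p = 0.0697, permutation test) and without chromosomes II and X (0.81, adjusted p = 0.0983, permutation test), where 3 of its 9 genes lie.

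Ribosomal protein genes had higher promoter ratios on average but not in every library. Of 129 genes, 94 lay above the host median, and the list differed by 0.52 ± 0.75 (SD, n = 5, permutation test, adjusted p = 0.00024). The values by library were 0.19 in YAC1, 0.49 in YAC2, 1.35 in YAC3, -0.52 in YAC6 and 1.099 in YAC7, so the direction turned in YAC6. The values are higher in YAC2, YAC3 and YAC7, the libraries that stand apart from YAC1 and YAC6 in limma, than in those 2. Histone genes follow the same order (1.03, 1.22 and 1.36 against 0.85 and 0.43), and galactose genes the opposite one (0.89, 0.94 and 0.92 against 1.01 and 1.08). Without YAC3 the mean was 0.32, and without YAC6 it was 0.78, each still past the threshold. RPS31 (-3.50 ± 0.33), which encodes a ubiquitin fusion, and RPS21A (-3.37 ± 0.26) had the deepest promoters, and RPS8A the highest ratio (1.15 ± 0.37) on the displaced part of chromosome II.

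The remaining lists did not pass 0.05 against random host sets. Heat shock and stress genes differed by 0.52 ± 0.11 (SD, n = 5, permutation test, adjusted p = 0.0716), with 15 of 20 above the median. The Hsp70 gene SSA1 was at -3.44 ± 0.85, and the trehalose synthase gene TPS1 (-2.59 ± 0.92) and the Hsp70 gene SSA3 (0.72 ± 0.35) both lie on the displaced part of chromosome II. Glycolysis and fermentation genes differed by 0.14 ± 0.25 (permutation test, adjusted p = 0.708), with 8 of 13 above, and by 0.08 without YAC2 and 0.24 without YAC6. PFK2, of phosphofructokinase, was at -3.32 ± 0.14, PGI1, the phosphoglucose isomerase gene on the displaced part of chromosome II, at -3.20 ± 0.07, and TDH1, a glyceraldehyde-3-phosphate dehydrogenase gene on the displaced part of chromosome X, at 0.81 ± 0.37. General regulatory factors and remodellers differed by -0.18 ± 0.21 (permutation test, adjusted p = 0.572), with 9 of 17 below. SWR1, of the H2A.Z exchange complex, was at -3.33 ± 0.20, MCM1 at -3.07 ± 0.44 and CBF1, on the displaced part of chromosome X, at -0.23 ± 0.20. URA3 (-2.88 ± 0.33) and TRP1 (-1.22 ± 0.14), the auxotrophic markers used to select YACs, gave a list difference of -0.06 ± 0.16 (permutation test, adjusted p = 0.816), which was -0.10 without YAC1 and -0.0015 without YAC3. Vector copies of the markers, where present, would add to their signal. With a pseudocount of 0.5, the 8 lists past 0.05 stayed past it with differences from -0.21 to 0.86.

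**Figure D3:**
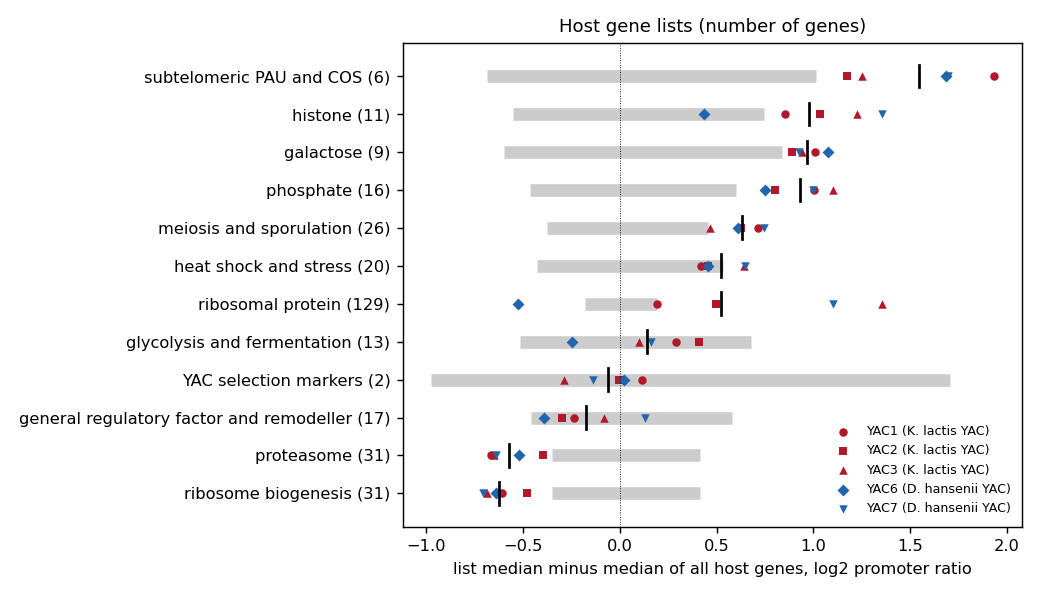
Median log2 promoter ratio of each of 12 host gene lists minus that of all host genes, with 1 point per library, a black tick for the mean of 5 libraries and a grey bar for 95% of random host sets of the same size. Means run from -0.62 for ribosome biogenesis to 1.55 for the PAU and COS genes, and the ribosomal protein points spread from -0.52 to 1.35.

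Host promoters were also compared between strains carrying *K. lactis* and *D. hansenii* DNA. Of 5252 host genes, 0 passed an adjusted p of 0.05 in limma, and 7 had an unadjusted p below 0.05 (2 higher and 5 lower in the *K. lactis* strains). Adjusted over the list alone, 0 members of the 12 lists passed, and 0 of the 311 had an unadjusted p below 0.05. None of the genes named next passed the test (limma, adjusted p = 0.9999 each). COY1, which encodes a Golgi membrane protein, differed by 1.02 (SE 0.39). The values were -0.91 (SE 0.28) for YAR068W and -0.95 (SE 0.37) for ERV1, a sulfhydryl oxidase gene of the mitochondrial intermembrane space. The YAR068W value was -0.51 without YAC6 and -1.32 without YAC7. Simulated data took each gene's spread over the 5 libraries, with independent noise. In them, 131 of 200 genes changed by 2 on the log2 scale were recovered, and 0 of 200 changed by 1 or by 0.5. The real libraries share a structure that this noise lacks, and 7 genes below an unadjusted 0.05 are fewer than independent noise would give. The simulated rates therefore need not hold for the real libraries, and even sizeable changes may have gone undetected. Leaving out a library also gave 0, which at this power says nothing about stability. The count at an unadjusted p below 0.05 was 184 without YAC1 and 405 without YAC7, where 1 *D. hansenii* library is left and the spread comes from the *K. lactis* strains alone.

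In the tables, the foreign DNA was covered at 0.803 to 1.09 times the level of host DNA. Mean signal per insert gene over that of host genes was 0.979 in YAC1, 0.803 in YAC2 and 1.00 in YAC3, or 0.928 ± 0.109 (SD, n = 3), and 1.04 in YAC6 and 1.09 in YAC7, or 1.06 ± 0.0370 (SD, n = 2). No test was run on these ratios. The insert tables of YAC1 and YAC7 step in units 1.77 and 1.29 times those of their host tables, which a separate scaling would give. Counted in each table's own steps, the ratio was 0.552 in YAC1 and 0.844 in YAC7.

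Within the host, whole chromosomes differed in signal in 3 libraries. YAC1 and YAC6 were nearly flat, with the highest chromosome at 1.26 and 1.06 times the lowest. In YAC2, 5 chromosomes (VI, VII, VIII, XI and XV) lay at 0.554 to 0.659 of the host median and the other 11 at 1.05 to 1.47. In YAC3, 9 chromosomes (I, II, III, V, VI, XII, XIII, XIV and XVI) lay at 1.36 to 1.75 and the other 7 at 0.630 to 0.810. In YAC7, chromosome I lay at 2.39 and the other 15 between 0.917 and 1.17. Promoter ratios are taken within each gene, so a factor common to a chromosome cancels in them. The same classes enter the insert levels: over its low chromosomes, the insert stood at 1.41 in YAC2, 1.64 in YAC3 and 0.910 in YAC7, in steps.

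**Figure D4:**
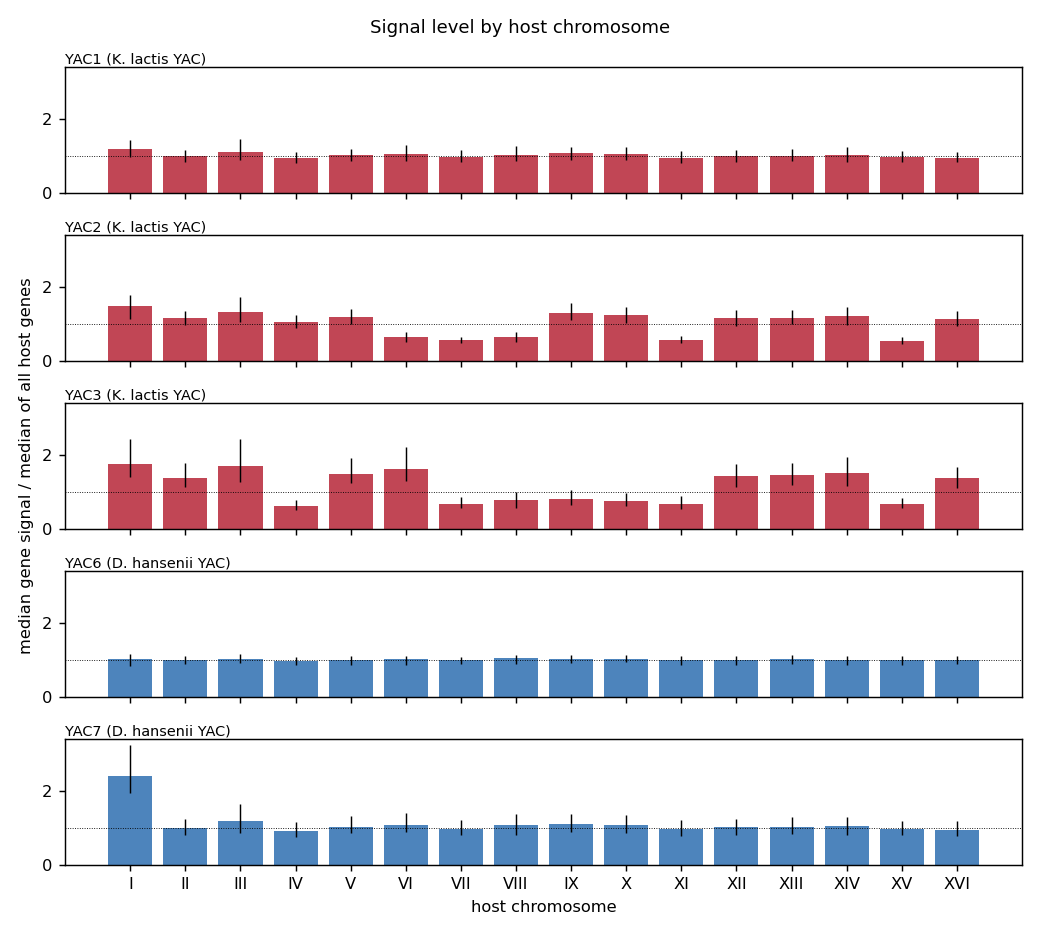
Median signal of the genes of each host chromosome over the host median of the library, for 5 strains (bar, median of the chromosome's genes; line, 25 to 75% of its genes). YAC2 and YAC3 each show 2 separate levels, YAC7 a raised chromosome I at 2.39, and YAC1 and YAC6 a single level.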

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

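Chosen after the results were seen were the 2 tests of start-site placement and the autocorrelation measure, while the comparison of the species was chosen before. Each value here is a difference between *K. lactis* and *D. hansenii* inserts, each taken relative to its host, that passed 0.05 by draws of host genes, which treat genes as units.

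The promoter difference was -0.68 (*K. lactis* minus *D. hansenii*), from shallower *D. hansenii* promoters at 1.21 above the host against 0.53. One candidate explanation is that the listed *D. hansenii* start sites are off by a common distance, but forward and reverse genes of both inserts matched the host profile best within 10 bp of no shift, against lags of 40 and 300 bp where host start sites are displaced. Start sites misplaced gene by gene could also fill an average promoter. The lowest 100 bp sought anywhere from -400 to +200 bp still differed from host genes by 0.96 (log2, permutation p = 2e-05). The gene-body window stayed at +100 to +500 bp of the listed start, where a misplaced depleted region would raise the ratio. This search therefore cannot exclude misplaced start sites. Whether the species matters also stays open, since the exact permutation p across the 5 strains was 0.1, the smallest this design allows, with 1 library per strain and other genes in each insert.

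The position of the +1 nucleosome differed by -20.6 bp between the species (permutation p = 2e-05 by gene draws, the smallest they can give, exact permutation p = 0.1 across strains), with YAC7 at 11.9 bp downstream of its host and YAC1 at -20.2 bp. Nucleosome spacing differed by 5.003 bp (permutation p = 0.00816 by gene draws, exact permutation p = 0.3 across strains), and the sign of the *D. hansenii* value depends on YAC7 (1.00 bp without it). For YAC7 the spacing draws spread over -2.55 to 2.57 bp, against -15.05 to 45.45 bp by bootstrap over insert genes. Array amplitude differed by 0.29 (log2, permutation p = 2e-05 by gene draws, exact permutation p = 0.1 across strains), with 3 of 3 *K. lactis* inserts closer to their host than both *D. hansenii* inserts. The autocorrelation peak of single genes differed by 0.0690 (permutation p = 0.0412 by gene draws, adjusted p = 0.0495), with an exact permutation p of 0.3 across strains.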

How the results depend on the processing

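Settings added after the data were seen are the neighbouring host sets, moved windows, centring, the host without chromosomes II and X, genes without runs of 0, autocorrelation spacing and levels in steps. The cause was not tested except where stated. Apart from leaving out a strain, 199 values of the main results kept direction and side of the threshold, 10 lost and 2 gained a call, 9 turned and 1 moved. Of values for single genes and strains, 166 stayed within their yardstick and 140 moved further. That was the SD between libraries for list genes and the median of such SDs over host genes for insert genes. For strain levels it came from the bootstrap interval, and for limma genes it was direction and side of the threshold. Promoter differences kept both in all but the neighbouring sets, at 0.23 to 0.71 for *K. lactis* and 0.63 to 1.51 for *D. hansenii*. Against neighbouring host sets, calls were lost for the promoter (0.53, permutation p = 0.256; 1.21, 0.0828), *K. lactis* gene bodies (0.12, 0.0534), *D. hansenii* +1 position (5.92 bp, 0.441) and spacing (-2.67 bp, 0.0650). With chromosomes II and X left out, only the gene-body call stayed lost (0.11, permutation p = 0.0581). Leaving them out changed the random range and the differences together, which were not told apart. The promoter difference went from 0.69 to 0.78 in YAC1 and from 1.54 to 1.67 in YAC6. The host without chromosomes II and X also turned the mean spacing of 5 strains (-0.109 bp in both host settings) and the marker list (0.038), and ended the galactose call (0.81). The window from -150 to -1 bp ended the galactose (0.79) and histone (0.73) calls and turned glycolysis (-0.073). *D. hansenii* gene bodies passed with 50 bp stretches (0.17) or means (0.11), and the species difference in gene bodies turned without host subtraction (-0.13). Autocorrelation turned spacing (-0.147 bp, 0.878 bp), genes without runs of 0 ended the *D. hansenii* call (-1.05 bp), and SD 30 bp (-0.430 bp) and unscaled profiles (-0.856 bp) turned the mean of 5. The mean insert level of 0.982 was 0.848 in steps.

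Leaving out a strain kept 125 values, turned 5, and lost 2 and gained 3 calls. The ranges were -0.107 (without YAC7) to 11.9 bp for *D. hansenii* +1, -11.0 (without YAC7) to -2.97 bp (without YAC1) for all +1, -6.34 to 1.00 bp (without YAC7) for *D. hansenii* spacing, 1.301 to 4.21 bp (without YAC2) for *K. lactis* spacing, -0.682 (without YAC1) to 2.01 bp (without YAC7) for all spacing, -0.0605 (without YAC3) to -0.0121 (without YAC2) for the *K. lactis* autocorrelation peak, 0.0775 (without YAC1) to 0.139 for *K. lactis* gene bodies, 0.00375 to 0.131 (without YAC6) for *D. hansenii* gene bodies and -0.0146 (without YAC6) to 0.113 for the species difference there. The species difference at promoters ranged from -1.003 to -0.36 (without YAC6). Limma gave 0 genes in all settings (unadjusted 2 to 405), a floor that says nothing about stability. Centring each library on its median moved the median difference of all genes from 0.10 to -0.05. The count model was not run on scaled coverage. No paired analysis was possible because the strains share no pairing. YAC3 was the coarsest library, at 396 steps, and depth in reads is unknown.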

Other observations

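Chosen after the results were seen were the tests of the scaling steps and of the ratio between chromosome levels, while the shift-back tests of chromosomes II and X and the comparison of the left and right side of each chromosome were set down before their outcome was seen.

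Host promoters of most of chromosomes II and X looked filled in the tables: the median promoter ratio over 5 libraries was 0.06 ± 0.06 on X and -1.62 ± 0.15 on II (SD, n = 5), against -2.27 to -2.02 on the other chromosomes. From CIS3 rightward on X (273 of 319 genes), profiles matched the other chromosomes best at lags of -300 bp for forward and +300 bp for reverse genes (-320 and +320 bp in YAC3), and from SSA3 rightward on II (339 of 365 genes) at -40 and +40 bp in all 5 libraries. Moved back by these lags, medians of both right parts lay within -0.16 to 0.12 of the other chromosomes, which is what start sites listed on a shifted coordinate would give. A chromatin difference of these right parts would have left a gap above 0.3, and the highest left was 0.12, whereas the 46 genes of the left part of X, at a lag of 0 in 4 libraries and of 20 bp in YAC3, lay above the other chromosomes by 0.07 in YAC7 to 0.42 in YAC6, which was not explained. A candidate source is a sequence difference between genome versions to the left of CIS3 and SSA3, which no table here can place.

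Whole chromosomes had raised signal in YAC2, YAC3 and YAC7, in ratios of 2.09, 2.19 and 2.35 between the high and low classes. Separate scaling of chromosomes is argued against by the steps: at least 33.9% of the values on the high chromosomes were odd multiples of the library's unit. Uneven recovery along chromosomes is argued against by the left and right sides, whose median ratio reached 1.07 at most, although single chromosomes reached 1.31. Extra copies of whole chromosomes may account for the separate classes, but the ratio of 2.35 for chromosome I of YAC7 lies above the bound of 2.3 set for it, so that this stays open. The design holds no group for chromosome number, and no further explanation was tested.

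In limma, the host libraries also split in another way than by insert species. When all 10 ways of setting 3 libraries against 2 were fitted with limma, YAC2, YAC3 and YAC7 against YAC1 and YAC6 gave 579 host genes past an adjusted 0.05, while the real grouping gave 0 (7 at an unadjusted p below 0.05) and the other 8 gave 0 as well (4 to 952 at an unadjusted p below 0.05). This points to a structure of the samples, and several measures follow it. YAC2, YAC3 and YAC7 are the 3 libraries with chromosome classes, the 3 coarsest (559, 396 and 726 steps, against 1739 and 1479) and those with the shallower host medians (-1.76, -1.74 and -1.89, against -2.28 and -2.27). These cannot be separated with 5 libraries. Correlations across host genes do not follow the split throughout: for promoter ratios YAC1 reached 0.917 with YAC6, but also 0.912 with YAC2 and 0.908 with YAC7, and over all bins 0.906 with YAC7 against 0.830 with YAC6, genes not being independent replicates. The lowest for promoter ratios was 0.559 (YAC3 with YAC6).

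Forward host genes had their +1 nucleosome upstream of that of reverse genes by -14.8 bp in YAC2 and -23.1 bp in YAC3, against -3.64, -3.46 and -3.81 bp in YAC1, YAC6 and YAC7, without chromosomes II and X. Averaged over both orientations, insert minus host was -19.3, -4.77 and -17.0 bp for *K. lactis* and 0.751 and 12.8 bp for *D. hansenii*. Signal over the selection marker URA3 was 1.52, 2.03, 2.67, 1.82 and 2.00 times the host median in YAC1, YAC2, YAC3, YAC6 and YAC7, and over TRP1 it was 1.53, 1.85, 1.345, 1.69 and 1.90 times. These values include the level of the chromosome: over the median of its own chromosome, chosen after the data were seen, URA3 stood at 1.49, 1.69, 1.80, 1.81 and 1.94, and TRP1 at 1.63, 1.755, 2.13, 1.73 and 2.07.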
